A study of Mus musculus with 2 samples.

How the data were processed

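Total RNA from quadriceps of 1 WT and 1 NF90-NF45 dbTg sample was labelled with Cy3 and hybridised to single-colour miRNA arrays, per the labels' protocols. The arrays were of 1 design, on the same slide and from the same scan, per the file headers. Spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, with background subtraction and spatial detrending but no scaling between arrays. The authors deposited 1 file of spot intensities per array. A table of processed values also comes with the series.

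Values were computed as follows, with the main choices made before the data were examined. Control spots and spots marked as outliers were left out, and no miRNA spot was saturated. The processed signals of the remaining spots of a probe, 6 to 40 on the WT array, were averaged. A probe was called detected on an array when at least 0.5 of its spots were well above background by Feature Extraction's flag. Each array was divided by the 75th percentile of its probes detected on both arrays, which was 882 for WT and 1220 for dbTg. This scaling suits miRNA arrays, where most probes are dark. Values were then put on the log2 scale. The log2 ratio of a miRNA is the mean over its probes detected on both arrays of dbTg minus WT. Its spot SE comes from the spread of spots around each probe's mean. The median coefficient of variation between spots of a detected probe was 6.85% on the WT array and 6.68% on the dbTg array. Only mouse miRNAs entered the comparison. Probes for 57 viral miRNAs were set aside.

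A miRNA with no detected probe on an array has only a bound there. Its fold was computed against the higher of the lowest detected signal of that array and the dim probe's own signal, and is given as "at least". No fold is given where this was under 1.

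The number of arrays limits the precision. With 1 array per genotype there was no statistical test, and miRNAs were counted by a fixed size of at least 2-fold (log2 ratio of at least 1 or at most -1). Lists of miRNAs were fixed before the data were examined and cover 18 families, cell types and processes. They were matched by the exact name in the files or by an older name. For lists with at least 3 members detected on both arrays, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 5 bins of mean signal. A rule for naming miRNAs was also set beforehand. It takes all members of the myogenic, miR-7, erythroid and Microprocessor-independent lists, the 10 highest and 10 lowest log2 ratios, the 3 highest bounds in each direction, and the highest and lowest member of each other list. In the report, miR-365, miR-193b, miR-223, miR-155, miR-21, miR-31, miR-34c, miR-222, miR-379, miR-154, miR-181c, miR-299*, miR-3070b-3p, miR-3072*, miR-133a*, miR-30a*, miR-652, miR-652* and miR-126-5p fall outside it and were chosen after their values were seen. Names are those of the array design and follow older miRBase usage, in which an asterisk marks the less abundant arm. Probes of different miRNAs were compared base by base, and 53 of the 175 miRNAs had a probe within 1 mismatch of another miRNA's probe. Genome positions are those the files give for the probes, on mm9.

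The processed table was set against the scanner files. Its values are linear intensities. For 76.7% of the miRNAs above its lowest value on WT and 75.5% on dbTg, the deposited value equals Feature Extraction's total gene signal divided by 1 constant per array, within 0.1%. The constants are 74.3 for WT and 154 for dbTg, a ratio of 2.07 where the main scaling has 1.38. These ratios are for unlike signals, since the main scaling divides the mean processed signal of spots. The origin of the constants is not given in the sources used here. Most miRNAs sit at the lowest value of their column, 821 for WT and 774 for dbTg, and the column medians are at that value, 0.00135 and 0.00065.

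Alternatives were other scalings (75th percentile of all miRNA probes, median of detected probes, none, quantile, positive control probes), normexp background correction with an offset of 50, the brightest probe per miRNA, Feature Extraction's total gene signal, the authors' processed values, a stricter and no filter on dim probes, thresholds of 1.5-fold and 3-fold, and a demand for 2 probes of 1 sign. Alternatives added after seeing the data were scaling on spike-in probes, rescaled processed values and the injury list without miR-206. So were lists with 1 value per transcript and arm pairs whose main arm entered 1 pair only. For 1 value per transcript, members from 1 hairpin, 1 genomic cluster or with near-identical probes were averaged, and random lists were drawn from the 100 such units.

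The scripts were tested on simulated data made from the real probe means and spot spreads, with a second array 1.4 times as bright. Of 180 miRNAs in that comparison of dbTg against WT, all 30 simulated at 3-fold and all 30 at 4-fold were counted in the right direction. None of 30 at 1.5-fold and none of 90 left unchanged was counted. The simulation holds spot noise only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.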

Results

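The data come from quadriceps, a large thigh muscle, of female mice aged 15 to 16 weeks. One animal group was wild type (WT) and the other carried transgenes for both NF90 and NF45 (dbTg). NF90 and NF45 are partner proteins that bind double-stranded RNA. Their complex is known to bind primary miRNA transcripts and to hinder the Microprocessor, the nuclease complex that releases miRNA precursors from them. The comparison asks how the levels of mature miRNAs in muscle differ when both proteins are overproduced. Each genotype was measured on 1 single-colour array, so there are no replicates. No test was possible, and each difference below is one between 2 RNA samples. The labels do not say whether each sample came from 1 animal or a pool. Errors are spot standard errors (spot SE), which cover only the spread between copies of a probe on an array. Each array held 43200 spots for miRNAs, from 2780 probes. On the WT array 6454 of these spots (14.9%) were well above background, against 7639 (17.7%) on the dbTg array. Of 1023 mouse miRNAs, 175 were detected on both arrays, 36 on the dbTg array alone, 5 on the WT array alone and 807 on neither. The mRNAs of the transgenes themselves were not analysed here.

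The muscle-specific miRNAs went in opposite directions in dbTg quadriceps. miR-206, a miRNA of muscle satellite cells and regenerating fibres, was 17.3-fold higher (log2 ratio 4.11, spot SE 0.015). miR-1, miR-133a and miR-133b were lower, with log2 ratios of -0.93, -1.14 and -0.94. Under quantile normalization these were -0.14, -0.54 and 0.00, so their size depends on the scaling. In the main comparison, miR-206 and miR-133a of the 4 passed the 2-fold size set for counting, but miR-133a fell short of it under quantile normalization, without scaling (-0.67) and with scaling on spike-in probes (-0.85), the last chosen after seeing the data. With scaling on all miRNA probes or on positive control probes all 3 were at least 2-fold lower, the highest at -1.10 and -1.23. Across the array, 18 of the 175 miRNAs were at least 2-fold lower in dbTg and 20 were at least 2-fold higher.

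**Figure D1:**
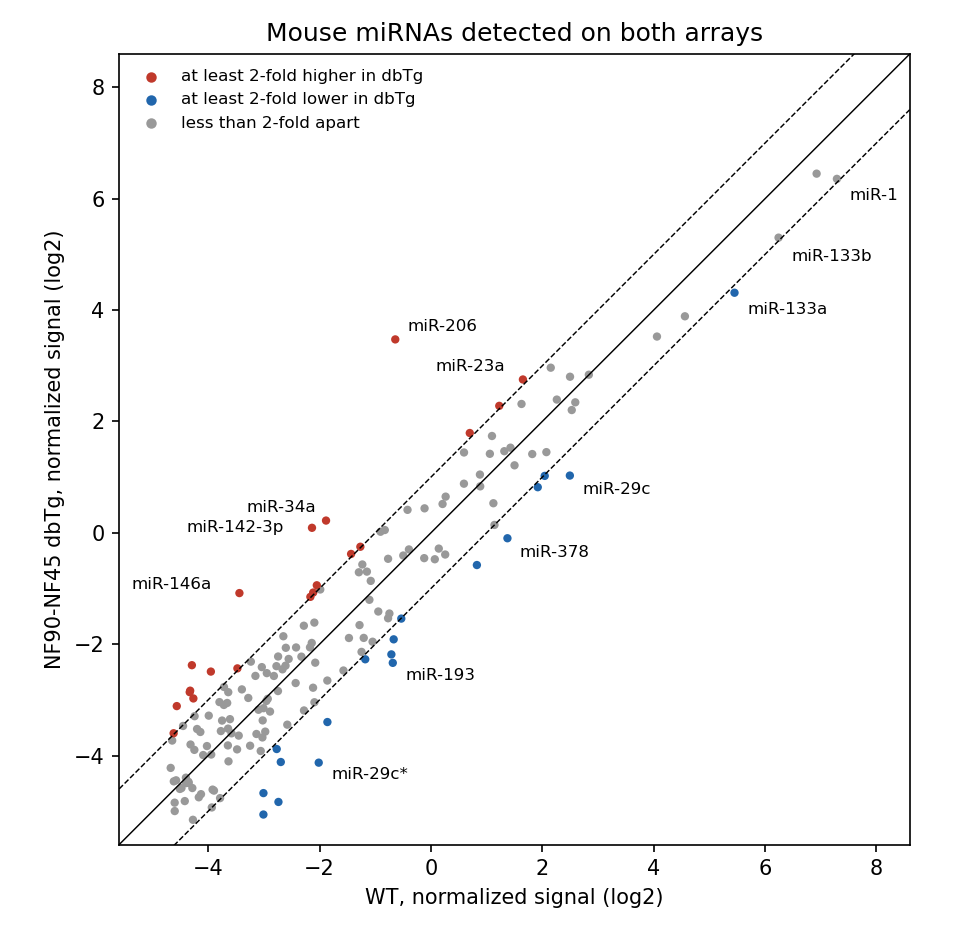
Normalized signal (log2) of each mouse miRNA detected on both arrays, WT on the x axis and NF90-NF45 dbTg on the y axis. Each point is 1 miRNA, the solid line marks equal signal and the dashed lines mark 2-fold differences. miR-206 stands farthest above the line at a log2 ratio of 4.11, while miR-1, miR-133a and miR-133b lie below it at the bright end.

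Among the 10 miRNAs with the highest ratios, after miR-206 came miR-146a, an inhibitor of innate immune signalling, at 5.12-fold higher (log2 ratio 2.36, spot SE 0.042). Only 1 of the 2 probes of miR-146a was detected on the WT array. Its log2 ratio ranged from 1.55 to 2.83 over the alternatives. miR-142-3p, a miRNA of blood cells, was 4.68-fold higher. miR-34a, a target of p53, was 4.30-fold higher, and miR-342-3p was 3.77-fold higher. The other 5 had log2 ratios from 1.29 to 1.49. They were miR-24-2*, miR-335-5p, miR-362-3p, miR-532-5p and miR-3473. With normexp background correction these came to 0.53, 0.51, 0.63, 0.42 and 0.42, and miR-342-3p to 0.85, all short of 2-fold. That setting counted 12 miRNAs as lower and 7 as higher.

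Among the 10 miRNAs with the lowest ratios, the miR-29c hairpin, whose mature product restrains collagen genes, gave a log2 ratio of -2.11 for its second arm, miR-29c*, and -1.47 for miR-29c. miR-486* was 4.27-fold lower and miR-3107* was 4.14-fold lower, with miR-3107, listed in later miRBase releases as miR-486b, at -1.47 on the log2 scale. miR-486 is enriched in muscle and promotes growth signalling through PI3K and Akt. The probes of miR-486* and miR-3107* differ by at most 1 base, so these are not independent readings. miR-378, which lies in the gene of the mitochondrial coactivator PGC-1β, was 2.77-fold lower (log2 ratio -1.47, spot SE 0.011). miR-434-3p, miR-193, miR-1-1* and miR-185 completed the 10, with log2 ratios of -1.67, -1.65, -1.54 and -1.42. miR-434-3p and miR-185 came to -0.99 and -0.95 with normexp correction, miR-185 and miR-29c to -0.95 and -0.999 without scaling, and miR-1-1* to -0.89 without the filter on dim probes.

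How many miRNAs counted as lower or higher depended on the scaling between arrays, because the signal of most miRNAs was higher on the dbTg array. Without scaling, the median miRNA had a log2 ratio of 0.47, with 8 miRNAs lower and 49 higher. Scaling on all miRNA probes gave 31 lower and 10 higher with a median of -0.16. Scaling on positive control probes gave 35 and 9, with a median of -0.30. Most of those probes belong to the control sets hur_1, hur_2, hur_4, hur_6 and mr_1. Without scaling these sets were themselves brighter on the dbTg array, by 0.79 to 1.77 in log2 ratio. The authors' own processed values gave 34 and 13, with a median of -0.17. Scaling on the spike-in probes, chosen after seeing the data, gave 11 and 35 with a median of 0.30. All 38 miRNAs counted in the main comparison kept their direction under each of these scalings. Division by 1 factor could not have reversed them, since it moved all miRNAs alike by at most 0.47 on the log2 scale. Only 19 of the 38 kept the 2-fold size under normexp correction. Values below are relative to a median of 0.00.

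Among the myogenic miRNAs, 1 of the 4 detected on both arrays was at least 2-fold higher and 1 was at least 2-fold lower. Their median log2 ratio was -0.94, which lay at percentile 3.22 among 10000 random lists of the same size matched on signal, as a description of these 2 arrays. Because of miR-206 alone, their mean was above 0, at 0.27. Under quantile normalization the median was -0.068. There miR-133b came to 0.00, since its probes have the same rank on both arrays. miR-499, which is encoded in a slow myosin gene, was detected on the dbTg array only, at least 1.81-fold higher. miR-208a and miR-208b, from the cardiac and slow myosin genes, were not well above background on either array. miR-486a-5p matched no name on the array, so the list leaves it out. The probes of miR-3107, at -1.47, match both strands of 1 place on chromosome 8. There miR-486* also maps, so these probes may read miR-486a-5p too. Counting miR-499 at its bound gave a median of -0.93.

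The miR-206 gene and the miR-133b gene lie close together. In the mm9 mouse genome build, the part of miR-206 that its probes match lies on the plus strand of chromosome 1 from 20669143 to 20669157, and that of miR-133b from 20672919 to 20672936. Together they span 3794 bases. Both probes of miR-206 showed the difference, with log2 ratios of 4.09 and 4.14, and the mean signal over its probes was 575 on the WT array and 13822 on the dbTg array. miR-1 and miR-133a are each encoded at 2 loci, on chromosomes 2 and 18. The probes of miR-133a and miR-133b differ by at most 1 base, so these are not independent readings either.

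Of the 9 miRNAs detected on both arrays in the list for oxidative metabolism and muscle growth, 3 were at least 2-fold lower and none was at least 2-fold higher. The lowest was miR-378, and miR-365 and miR-193b, which share a transcript known from brown fat, had log2 ratios of -1.40 and -1.24. However, miR-365 is also encoded at a second locus, on chromosome 11. The highest member was miR-107, at 0.22. The list median was -0.53, at percentile 10.2 of matched random lists, inside their central 95%.

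In the list of muscle injury and regeneration, 8 of 13 miRNAs were detected on both arrays and 2 on neither. Of the 8, 3 were at least 2-fold higher and none was at least 2-fold lower. Besides miR-206 these were miR-335-5p and miR-223, at 1.47 and 1.11 on the log2 scale. miR-155 and miR-21 had log2 ratios of 0.95 and 0.81, and the lowest member was miR-494 at -0.051. The median of 0.88 lay at percentile 99.3. Without miR-206, a choice made after seeing the data, it was 0.81 at percentile 97.6, or 96.7 with 1 value per transcript. With miR-31, miR-34c and miR-222, detected on the dbTg array only, at their bounds the median of the whole list was 0.78. This list shares miR-21, miR-494, miR-223, miR-155 and miR-206 with other lists.

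Immune-cell and fibroblast miRNAs were higher as well, the latter mostly by under 2-fold. All 5 immune-cell miRNAs detected on both arrays had ratios above 0, and 3 were at least 2-fold higher. They were miR-146a, miR-142-3p and miR-223, the last a miRNA of neutrophils and other myeloid cells. The lowest was the lymphocyte miRNA miR-150, at 0.26. It came to -0.036 with scaling on positive control probes. miR-142-5p, the other arm of the miR-142 precursor, was detected on the dbTg array only, at least 4.18-fold higher. The immune-cell median of 1.11 lay at percentile 99.5. All 7 fibroblast miRNAs had ratios above 0, from 0.54 for miR-140 to 1.04 for miR-214, and 1 of them was at least 2-fold higher. Their median of 0.81 lay at percentile 98.4, but several share a transcript or have near-identical probes. With 1 value for each of their 3 transcripts, an alternative chosen after seeing the data, the percentile was 92.1. For the 5 immune-cell miRNAs, each from its own transcript, it was 98.7.

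Markers of blood vessels and red cells did not share this direction as a group. The vascular list had a median of -0.37 over 4 miRNAs from 2 transcripts, at percentile 20.1, and of 0.10 without scaling. Its members ranged from -0.65 for miR-145, a smooth muscle miRNA, to 0.13 for the endothelial miR-126-3p. The erythroid miRNAs miR-451 and miR-144, from 1 transcript, had log2 ratios of -0.29 and -0.27. Their median of -0.28 became 0.19 without scaling and 0.015 with scaling on spike-in probes. miR-144-5p matched no name on the array, and miR-144*, the second arm of the miR-144 hairpin, was not well above background on either array. Of 11 miRNAs of liver, neurons, epithelium and islets, miR-192 was detected on both arrays, at 0.92, 4 others on the dbTg array only and 6 on neither. The bounds of those 4 reached at most 1.16-fold, so this list gives no direction.

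**Figure D2:**
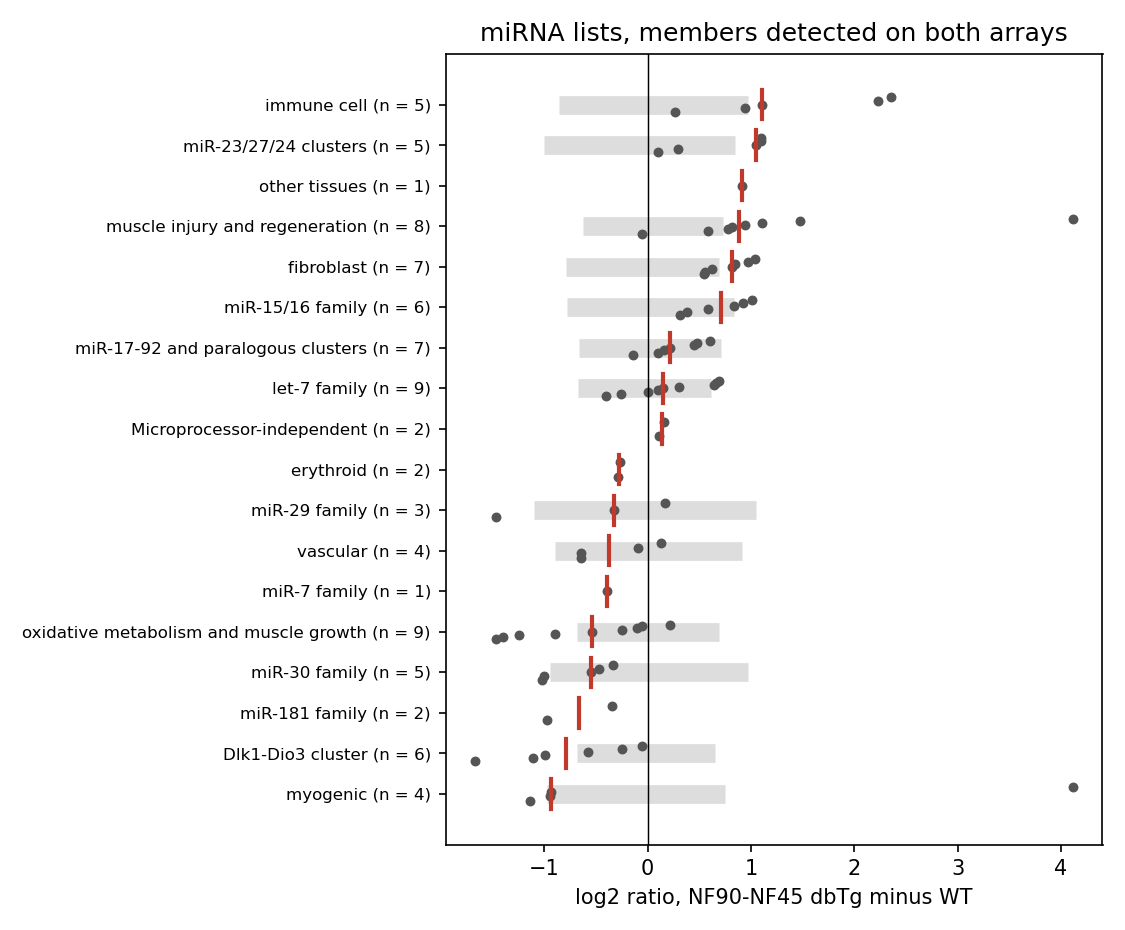
Log2 ratio (dbTg minus WT, x axis) of the members of each miRNA list detected on both arrays, with 1 row per list. Grey points are miRNAs, red bars are list medians and pale bands span the central 95% of medians of matched random lists, drawn for lists of at least 3 members. The immune-cell median of 1.11 and the fibroblast median of 0.81 lie to the right of their bands, and the Dlk1-Dio3 median of -0.79 to the left.

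In several miRNA families most or all members lay on 1 side of the median. The miR-23/27/24 clusters had 3 of 5 members at least 2-fold higher and a median of 1.05, at percentile 99.4. Its members come from neighbouring genes or have near-identical probes and make up 1 joined group, so the percentile counts related readings as separate. Members ranged from 1.10 for miR-23a to 0.097 for miR-27b, which came to -0.068 with scaling on all miRNA probes. All 6 members of the miR-15/16 family, which restrains the cell cycle, were above 0, from 0.31 for miR-15a to 1.02 for miR-15b. Their median was 0.71, at percentile 94.0, or 82.6 with 1 value for each of 3 transcripts. By contrast, the 6 list members of the imprinted Dlk1-Dio3 cluster detected on both arrays were below 0, from -1.67 for miR-434-3p to -0.051 for miR-494. Of these, 2 were at least 2-fold lower, and the median of -0.79 lay at percentile 1.32, with the members joined in 2 groups. Of the members detected on 1 array only, miR-337-3p was at least 1.97-fold lower, miR-379 at least 1.08-fold higher and miR-154 without a fold. Outside the list but in the same part of chromosome 12, miR-299*, miR-3070b-3p and miR-3072* had log2 ratios of -0.56, -0.081 and 0.68. All 5 members of the miR-30 family were below 0, from -1.02 for miR-30a to -0.33 for miR-30b, with a median of -0.54 at percentile 17.3. miR-494 and miR-30b came to 0.42 and 0.13 without scaling.

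The let-7, miR-17-92 and miR-29 medians lay nearer to 0. The let-7 family, from -0.40 for let-7d to 0.69 for let-7c, had a median of 0.15 at percentile 71.0, which became -0.017 with scaling on all miRNA probes, -0.15 with scaling on positive control probes and -0.024 in the authors' values. The miR-17-92 group of clusters, from -0.14 for miR-93 to 0.60 for miR-19a, had a median of 0.21 at percentile 53.1, which became -0.084 with scaling on positive control probes. The miR-29 family had a median of -0.32 at percentile 37.0, which became 0.14 without scaling. Within it, miR-29b at 0.17 and miR-29c at -1.47 differed, and miR-29b came to -0.13 with scaling on positive control probes. miR-181a and miR-181b, whose probes differ by at most 1 base, had log2 ratios of -0.35 and -0.98. Their median of -0.66 became -0.35 when miR-181c, detected on the dbTg array only and at least 1.02-fold higher, was counted at its bound. miR-181a came to 0.12 without scaling.

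miR-7 is the miRNA whose primary transcript is best known to be bound by NF90 and NF45. miR-7a had a log2 ratio of -0.40 (spot SE 0.066), which became 0.072 without scaling, and miR-7b was not well above background on either array. The second arm miR-7a-1* was detected on the WT array only, at least 2.02-fold lower in dbTg under the main scaling. The readings of miR-7a and miR-7a-1* each rest on 1 of 2 probes, near the lowest detected signal. Their WT log2 signals were -4.60 and -4.23, where the lowest detected was -4.67. Of the miRNAs made without the Microprocessor, miR-320 and miR-1224 had log2 ratios of 0.15 and 0.11, a median of 0.13 that became -0.031 with scaling on all miRNA probes and -0.16 with scaling on positive control probes. miR-484, miR-877, miR-877* and miR-702 were not well above background on either array. miR-702-5p and miR-1224-3p matched no name on the array, and the second arm miR-1224* was not well above background either.

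Among the 41 miRNAs detected on 1 array only, the bounds were largest for miR-142-5p, miR-34b-5p and miR-706 on the dbTg array. These were at least 4.18-fold, 2.02-fold and 1.89-fold higher. On the WT array they were largest for miR-7a-1*, miR-467b* and miR-337-3p, at least 2.02-fold, 1.98-fold and 1.97-fold lower in dbTg. All these bounds are for the main scaling and shift with it. A bound over 1-fold could be given for 22 of the 36 miRNAs on the dbTg array and for all 5 on the WT array.

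The arms of 1 precursor gave similar ratios. Over 18 pairs of arms both detected, Pearson's r was 0.86 and Spearman's rho 0.86, and 16 pairs had the same sign. Without the filter on dim probes r was 0.23. This is a correlation across miRNAs, which are not independent replicates. Re-pairing arms at random gave r between -0.45 and 0.47 in 95% of 10000 draws, and r was 0.82 without the 2 pairs farthest from the median. miR-133a and miR-133a* had log2 ratios of -1.14 and -1.10, and miR-30a and miR-30a* of -1.02 and -1.09. The pairs of opposite sign were miR-652 with miR-652*, at 0.38 and -0.68, and miR-126-5p with miR-126-3p, at -0.095 and 0.13. These 2 pairs were singled out after their values were seen. With scaling on all miRNA probes miR-126-3p came to -0.03, so the miR-126 arms then had 1 sign.

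Spot noise was small beside the larger of these differences. It was not small beside the smallest, such as miR-320 at 0.15 (spot SE 0.091) and miR-494 at -0.051 (spot SE 0.031). The median spot SE of a log2 ratio was 0.024 and the largest 0.12, and 129 of 135 miRNAs with at least 2 probes detected on both arrays had probes of 1 sign. The spread between animals was not measured, so that none of these differences can be set against it.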

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

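The tests in this part were chosen after the result was seen, and that of background was rewritten after its first values, which had left it open on raw signals. Signals outside the miRNA comparison stood out on 5 positive control probe sets of the array design, whose targets are not given in the sources used here. After the main scaling, the dbTg array was brighter than the WT array by 1.30 on the log2 scale for hur_6, 0.59 for hur_4, 0.54 for hur_2, 0.47 for mr_1 and 0.32 for hur_1. Their spot SE was at most 0.016. With scaling on all miRNA probes hur_6 came to 1.14, and hur_2, mr_1 and hur_1 to 0.37, 0.30 and 0.15. The authors' divisors belong to total gene signal. Applied to these processed signals they gave 0.72 for hur_6 and -0.04, -0.11 and -0.26 for hur_2, mr_1 and hur_1. Those values mix unlike signals, so that their signs are not a result.

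These controls belong to a wider pattern, in which the dbTg array had more detected miRNAs, 211 against 180, and a median unscaled log2 ratio of 0.47. Brighter labelling, hybridization or scanning as the whole cause would lift spike-in controls that pass through the same steps. However, their mean unscaled log2 ratio was 0.17 (SD 0.092 over 4 spike-ins). They ranged from 0.08 for dmr_3 to 0.29 for dmr_285, all below the median miRNA. Which steps each spike-in passed through was not examined, so labelling is not weighed apart from the other steps. For probes detected on both arrays, higher background is argued against by the raw signal of negative control spots, 80.3 units on WT and 81.0 on dbTg (SD 6.30 and 6.70). They differ by 0.72, and the mean local background differs by 5.54, against 46.1 for the median of 326 probes detected on both arrays. Dim probes detected on the dbTg array alone were not part of that comparison. A larger share of small RNA in the dbTg sample, a different amount of input RNA and the genotype stay open, and may each account for the rest. With 1 array per genotype they were not tested.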

How the results depend on the processing

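No paired analysis was possible because each genotype has 1 array and no result comes from a test. Of 285 values recomputed for the counts, list medians and arm correlation, 209 stayed within 1.5 times the main count, the SD of the list's members or the bootstrap interval of r. The SD is a wide limit for spread-out lists, such as 2.56 for the myogenic list, so for these the count says little. Of the 18 lists, 10 kept the sign of their median under every alternative, leaving out 1 value per transcript for lists joined into 1 or 2 groups. The 10 were the myogenic, miR-30, miR-15/16, miR-23/27/24, miR-181, oxidative metabolism, injury, fibroblast, immune-cell and Dlk1-Dio3 lists. However, the myogenic median was -0.068 under quantile normalization, and it turned to 0.27 when its members were averaged as 1 group. No miRNA named in the text with at least a 2-fold difference changed sign. Of 628 recomputed values of 49 named miRNAs, 498 moved by more than the 95% interval from spot SE, a narrow technical bound. Scaling by 1 factor shifts all miRNAs alike by construction, here by at most 0.47, so it could not reverse a 2-fold difference. For the other settings the cause was not tested. With 1 value per transcript, chosen after seeing the data, medians were 0.15 for let-7, 0.59 for miR-15/16, -0.39 for oxidative metabolism and 0.81 for fibroblast. Lists joined into 1 or 2 groups got no percentile. Their medians by this choice included 0.27 for myogenic, 0.73 for miR-23/27/24, -0.67 for miR-30 and -0.77 for Dlk1-Dio3. Dim probes limit the miR-7, Microprocessor-independent and other-tissue lists, which have 1 or 2 members on both arrays.

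At 1.5-fold there were 44 lower and 44 higher miRNAs, and at 3-fold 5 and 5, fewer by construction. The 75th percentile of all miRNA probes gave 31 lower and 10 higher, and medians of -0.56 for miR-7, -0.44 for erythroid, 0.75 for other tissues and -0.031 for Microprocessor-independent miRNAs. The median of detected probes gave -0.31 for erythroid and 0.10 for Microprocessor-independent miRNAs.

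Without scaling there were 8 lower and 49 higher. Medians were 0.62 for let-7, 0.072 for miR-7, -0.076 for miR-30, 1.18 for miR-15/16, 0.68 for miR-17-92, -0.19 for miR-181, 1.28 for fibroblast, 0.10 for vascular, 0.19 for erythroid, 1.38 for other tissues and 0.60 for Microprocessor-independent miRNAs. Quantile normalization gave -0.33 for erythroid, 0.78 for other tissues and 0.042 for Microprocessor-independent miRNAs.

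Scaling on positive control probes gave 35 lower and 9 higher. Medians were -0.69 for miR-7, 0.41 for miR-15/16, -0.084 for miR-17-92, 0.52 for fibroblast, -0.58 for erythroid, 0.62 for other tissues and -0.16 for Microprocessor-independent miRNAs. Scaling on spike-in probes, chosen after seeing the data, gave 11 and 35, with -0.10 for miR-7, 1.003 for miR-15/16, 0.51 for miR-17-92, 1.11 for fibroblast, 0.015 for erythroid, 1.21 for other tissues and 0.43 for Microprocessor-independent miRNAs.

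Normexp correction gave 12 lower and 7 higher, with medians of 0.52 for fibroblast, 0.11 for other tissues and -0.13 for Microprocessor-independent miRNAs. The brightest probe gave -0.26 for erythroid and 0.10 for Microprocessor-independent miRNAs. Total gene signal gave 36 lower, 12 higher and 67 on 1 array only, with -0.59 for miR-7, 0.56 for fibroblast, -0.56 for erythroid, 0.39 for other tissues and -0.13 for Microprocessor-independent miRNAs. The authors' values gave 34 and 13, with -0.57 for miR-7, -0.45 for erythroid and 0.24 for Microprocessor-independent miRNAs. Rescaled after seeing the data, they gave 36 and 13, with -0.68 for miR-7, 0.56 for fibroblast and -0.56 for erythroid.

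Requiring every spot well above background gave 26 lower and 7 higher, with medians of -0.44 for erythroid and -0.049 for Microprocessor-independent miRNAs. Without a filter on dim probes the arm correlation was 0.23, and the medians of other-tissue and Microprocessor-independent miRNAs were -0.57, because most of their members sit at the floor of both arrays.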

Other observations

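All the tests in this part were chosen after the result was seen, except those of position on the array and of probe GC content and length. The miRNAs in this paragraph and the next were picked after their values were seen. Neighbouring hairpins gave similar ratios at several places in the genome (mm9). On the X chromosome, between 6814874 and 6825569, miR-362-3p, miR-500 and miR-532-5p were all higher, with log2 ratios from 0.79 to 1.46. On chromosome 16, between 13449669 and 13454009, miR-193b and miR-365 were both lower, at -1.24 and -1.40. However, miR-365 has a second locus on chromosome 11, where miR-193 lies, at -1.65, so its reading cannot be assigned to 1 place. On chromosome 18, between 61807495 and 61808909, miR-143 and miR-145 had ratios of -0.65 each. miR-23a and miR-27a, on chromosome 8, had log2 ratios of 1.10 and 1.09, against 0.29 and 0.097 for their relatives miR-23b and miR-27b on chromosome 13. The second arms from these 2 places, which tell the loci apart, were 1.49 for miR-24-2* and 0.35 for miR-24-1*.

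The 20 brightest miRNAs included names that are now regarded as tRNA fragments, miR-720 and miR-1274a, with log2 ratios of -0.67 and -0.62. Of the probes for 57 viral miRNAs, 5 were detected on both arrays, with log2 ratios from -0.33 to -0.096, and 1 on the dbTg array only.

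A hypothesis is that arms and neighbours share the change of their transcript. The correlation between arms, r = 0.86, lay above the range of re-paired arms, although r was 0.23 without the filter on dim probes. It was 0.88 over the 14 pairs whose main arm entered 1 pair only. Among these, miR-1 and miR-133a still come from more than 1 locus each. For differently named hairpins of 1 cluster, leaving out near-identical probes, the mean absolute difference in log2 ratio was 0.55 over 70 pairs. In a cluster each miRNA lies within 10000 bases of the next. Some pairs are arms of 1 hairpin under different names, such as miR-199a-3p with miR-199b*, which span 59 bases. Both arms of a hairpin can also enter, so the 70 pairs are not independent and repeat part of the agreement between arms. Shuffled ratios gave 0.78 to 1.21 in 95% of 10000 draws. This is consistent with changes that act on transcripts or precursors, though the widest gap within a cluster was between miR-206 and miR-133b, at 4.11 and -0.94.

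The pattern of higher miR-206 with lower miR-1, miR-133a and miR-133b was weighed against the processing. Over 6 ways of dividing each array by 1 factor, the highest ratio of the 3 lowered miRNAs was -0.47. This argues against the scale factor only within the range of these 6, which moved all ratios alike by at most 0.47. The left and right sides of the array differed by at most 0.033 in log2 ratio, which argues against position. A signal-dependent difference between the arrays stays open for the 3 lowered miRNAs. Their 6 probes lay below the nearest probes of other miRNAs by a median of -0.48 (SD 0.16), but only 1 probe had 5 such probes within 1 log2 unit. Under quantile normalization miR-133b came to 0.00, miR-1 to -0.14 and miR-133a to -0.54. A muscle injury or regeneration response stays open too. The rest of that list, without miR-206, had a median of 0.81 at percentile 97.6 of matched random lists, but at 96.7 with 1 value per transcript, which is short of the limit set for it. The genotype's other effects were not tested.

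For the higher immune-cell and fibroblast miRNAs, a lower share of muscle fibre RNA would raise markers of all other cell types alike. However, the vascular median was -0.37 against 1.11 for the immune list and 0.81 for the fibroblast list. This counter-evidence is limited, since the vascular list rests on 2 transcripts. Its endothelial member miR-126-3p was at 0.13, and miR-192 from other tissues was at 0.92. More blood in the sample is argued against by the erythroid median of -0.28, led by the bright miR-451. That median rests on 1 transcript and became 0.19 without scaling. Brighter readings of dim probes would lift random lists matched on signal, and the immune median lay at percentile 99.5 of these, or 98.7 with 1 value per transcript. For the fibroblast miRNAs these were 98.4 and 92.1, so that such readings stay open there. After removal of the trend with probe GC content and length the immune median was 1.08 and the fibroblast median 0.72. More immune cells and fibroblasts in the dbTg muscle may account for the pattern as a hypothesis. However, 5 of 6 immune and 7 of 7 fibroblast members were also detected on the WT array, in whole-tissue RNA that does not show the cell of origin, so a change within cells stays open.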
